A study of Mus musculus with 7 samples.

How the data were processed

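RNA was measured by sequencing in the livers of C57BL/6 mice, a common inbred strain, at 3 months (4 samples) and 21 months (3 samples). Per the labels' protocols, total RNA was isolated with Trizol and RNeasy columns, mRNA was enriched on oligo-dT beads, fragmented and ligated to RNA adapters, and the strand-specific cDNA was amplified by PCR without molecular identifiers. The submitters' processing notes name TopHat, RSEM and edgeR and the mouse build mm9; their versions and roles are not given in the sources used here. The labels do not say that the samples of an age came from separate animals, so p-values here measure the spread between these samples, which may be technical. The labels give no sex, cage, time of sampling or feeding state.

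Each sample had 1 table with the same 23366 gene symbols. The tables hold estimated counts per gene, deposited by the authors under the name expected counts, of which 86.5% were whole numbers. The authors also deposited TPM values (relative transcript abundance), which sum to 1e+06 within rounding in each library. FPKM values, scaled for length and depth, were deposited beside them and were not used here. Per the file headers, the remaining columns give each gene's length and effective length, from which a median shortfall per library was computed as a sign of fragment length. Fragments themselves were not measured, and fragment length as a covariate means this shortfall below. Gene names are those of the files; 92.1% of them match a current symbol of the GRCm38.p6 gene table, which was used only to order neighbouring genes. No genome was used and no coordinates are given. An expectation-based count splits reads between near-identical genes, so values of the Mup, Cyp2b, Cyp2c, Cyp3a41, Sult2a, Hbb, Hba, Saa, H2 and histone families are uncertain for single members. The same holds for any other gene with a near-identical copy, and such genes are not marked below.

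Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr (minimum count 10, minimum total 15), leaving 11251 genes. Counts were scaled by TMM and tested with edgeR's robust quasi-likelihood test, 21 months against 3 months, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Every adjusted p of a single gene below comes from that test. A log2 fold change is 21 months minus 3 months, and its standard error is the fold change divided by the root of the test's F value. CPM are counts per 1e+06 scaled counts, given as mean ± SD with n = 4 at 3 months and n = 3 at 21 months. Analyses ran in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and figures in Python 3.11.15 with matplotlib 3.10.9.

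Libraries held 4724687 to 11143125 expected counts, and 3840574 to 8988306 without Rn45s, the 45S ribosomal RNA precursor. A count of 0 allows up to 3 counts, which is 0.257 to 0.607 CPM by library and 0.106 CPM over the 3-month group. For genes with 1 to 3 counts in a group, the ratio of group sums is given with an exact binomial interval at 95%. These floors and intervals cover counting error only, since PCR copies are not independent molecules. Each library counted as 1 sample; every pair differed by more than counting noise, which does not show that they came from separate animals.

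Before the data were examined, 37 gene lists were fixed from textbook knowledge: PPARA targets and fatty acid oxidation, lipid droplet and triglyceride storage, fatty acid synthesis, cholesterol synthesis and uptake, bile acid synthesis and transport, xenobiotic metabolism, male-biased and female-biased liver genes, the circadian clock, acute phase response, interferon response, MHC antigen presentation, oxidative phosphorylation, glucose metabolism, the unfolded protein response, NRF2 antioxidant genes, heat shock, immediate early genes, cytoplasmic ribosomal proteins, liver transcription factors, nucleosome remodelling and histones, pericentral and periportal genes, lysosome and autophagy, cell cycle, senescence and p53 targets, hepatocyte products, and markers of B, T and NK, macrophage, neutrophil, stellate, endothelial, bile duct, red, fat and exocrine pancreas cells. The 34 lists with at least 5 tested members were compared with all other genes by limma's camera with its preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists, and again with the correlation estimated from the data. Counts adjusted over the list alone are given beside those over all genes. Lists of ribosome biogenesis, adipose tissue transcripts, amino acid response and major urinary protein genes were written after the data were seen.

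Named genes were fixed by rule at the same stage: the 12 largest rises and falls past the threshold with a mean of at least 5 CPM and no overlap between ages, the 5 smallest p-values in each direction, up to 4 members of each list with the smallest adjusted p, and Foxa2, Hdac3, Ppara, Pparg, Srebf1, Cdkn1a and Cdkn2a. Any other gene named was chosen after its values were seen. Some genes that the rule takes are not reported here.

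The samples share replicate numbers 1 to 3 across ages. The deviations of same-numbered samples from their group means correlated across genes at 0.107, 0.174 and 0.104, each over the 0.1 set for treating the numbers as pairs, although 21 months replicate 1 correlated best with 3 months replicate 4 (0.159). The pairing therefore comes from the data, not from the labels, and a fit with the replicate number as a block over those 6 samples was run as an alternative. Other alternatives were RLE, upper-quartile and library-size scaling, DESeq2, limma voom with and without sample weights, limma on log2(TPM + 1), other filters on low counts, removal of abundant genes, unrounded counts, a non-robust fit, a test against a fold change of 1.5, and leaving out each sample. Removal of ribosomal RNA rows (with that of Lars2), the 6 paired samples without the block, and fragment length as a covariate were added after the data were seen.

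The steps were tested on simulated data drawn for this comparison from the real means, library sizes and dispersions. With 200 of the genes changed, edgeR's test over 11138 genes recovered 46.3% of those changed 1.5-fold, 80.6% of those changed 2-fold and 97.0% of those changed 4-fold, and 8.02% of its calls were unchanged genes. With no gene changed it called 3 of 11145 genes, and camera called 0 of 34 lists; with 1 list raised 1.5-fold it called 2. The simulated genes were independent, unlike real ones.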

Results

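Liver RNA was profiled in C57BL/6 mice at 2 ages, 3 months (n = 4) and 21 months (n = 3), by strand-specific sequencing of polyadenylated RNA. The comparison asks which liver transcripts differ between young adult and old mice. The 3-month libraries held 5932697, 11143125, 4724687 and 6498243 expected counts and the 21-month libraries 10458583, 6882935 and 8235677. Rn45s took 18.7% to 25.6% of the counts of a library, with no separation of the ages. The Lars2 row, removed with those of ribosomal RNA in an alternative, took 1.33% to 1.56% at 3 months and 1.63% to 2.55% at 21 months. The median shortfall of effective length was 34.4 to 38.8 bases in the 3-month libraries, and 35.4, 30.9 and 21.4 bases in 21-month replicates 1, 2 and 3. All 7 libraries expressed the Y-linked gene Ddx3y (22.5 to 40.2 CPM), and Xist stayed at or below 0.730 CPM.

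Of the genes tested in each list, 9 of 24 for lipid storage and 22 of 53 for foreign-compound metabolism were higher in old livers. Of 29 male-biased, 67 ribosomal protein and 30 unfolded protein response genes, 12, 16 and 5 were lower. In the order of these lists, 0, 2, 2, 2 and 0 genes went the other way. Shifts as large came in 4 of 35 splits for ribosomal protein and 3 for unfolded protein response genes, the real split included. None of the 34 lists passed camera with an estimated correlation. Of 11251 genes tested, 1274 differed between ages by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 615 higher and 659 lower at 21 months. Of these, 133 were at least 2-fold higher and 91 at least 2-fold lower. The ages did not overlap for 2718 tested genes, 24.2% against 5.71% by chance, and for 1230 of the changed genes. The first principal component held 43.1% of the variance and separated the ages (-27.8 to -16.1 at 3 months and 24.3 to 28.6 at 21 months). On the TPM scale, where the median of all genes lay 0.10 above 0 on the log2 scale, 74.6% of the calls were higher, against 48.3% here. The number of calls fell to 773, 834 and 745 without 3-month replicates 2, 3 and 4. It fell to 580 without 21-month replicate 3, whose shortfall of effective length was smallest, and to 332 with fragment length as a covariate. That covariate also ended the calls of 56 of the 120 named genes tested (edgeR adjusted p = 0.0511 to 0.456), among them Cd36, Cyp4a14, Vnn1, Serpina7, Egr1, Cdh1, Hspa1b, Pex11a, Srebf1, Pparg, Nudt7, Hamp2, Nr1d1, Nr1d2, H2-Q7, Igj, Cygb, Lyve1, Sox9, Alb, Ndufa13, Slc2a2, G6pc, Nqo1, Srxn1, Bag3, Gadd45g, Rpl35, Rps28, Chd1 and Rnf43. Of these 56, 31 had a log2 fold change at least as large with the covariate, and their median SE was 0.17 with it and 0.14 without.

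Among the 12 largest rises at a mean of at least 5 CPM were genes of lipid handling. Cidea, which coats lipid droplets, went from 2 counts in the 3-month group to 589 in the 21-month group, a ratio of 323 (95% counting interval 89.1 to 2677), and Cyp2b9, a cytochrome P450, from 1 count to 482, a ratio of 529 (94.5 to 20948). Cidec, a relative of Cidea, rose from 1.73 ± 1.40 to 19.5 ± 5.09 CPM (log2 fold change 3.60 ± 0.39 SE, edgeR adjusted p = 0.000889). Cyp4a14, a fatty acid hydroxylase, rose from 14.3 ± 11.9 to 238 ± 135 CPM (edgeR adjusted p = 0.0335), and Cd36, a fatty acid transporter, from 13.6 ± 4.32 to 70.3 ± 27.0 CPM (edgeR adjusted p = 0.0116). The protease inhibitor Serpinb1a rose from 2.89 ± 0.189 to 34.5 ± 16.5 CPM. Cyp2b10 rose 9.40-fold, the clock-linked gene Ccrn4l 5.19-fold, Lrtm1 4.74-fold, Raet1d 4.36-fold, the thyroxine carrier Serpina7 4.06-fold and the pantetheinase Vnn1 3.95-fold. The smallest p-values among rises also included Fitm1 (3.67-fold), the succinate receptor Sucnr1 (3.55-fold), Olig1 (2.64-fold) and Clec2d (2.20-fold). In the fits named next that leave out 1 library, the log2 fold change was 3.68 to 4.13 for Cyp4a14 (4.14 with all samples). It was 1.76 to 2.12 for Vnn1 (1.98) and 10.1 for Cyp2b9 (8.41). Those fits hold fewer samples, and some calls of rises were lost in them. That of Cyp4a14 was lost without 3-month replicate 1, 2 or 4 or 21-month replicate 1 or 3 (edgeR adjusted p = 0.0563 to 0.1001) and with the replicate block (0.0529). That of Vnn1 was lost without 3-month replicate 1, 2 or 3 or 21-month replicate 1 or 3 (edgeR adjusted p = 0.0564 to 0.0835), that of Raet1d without 3-month replicate 2 or 4 (0.0741 and 0.0850), that of Cyp2b9 without 3-month replicate 4 (0.146) and that of Serpina7 without 21-month replicate 3 (0.0564).

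**Figure D1:**
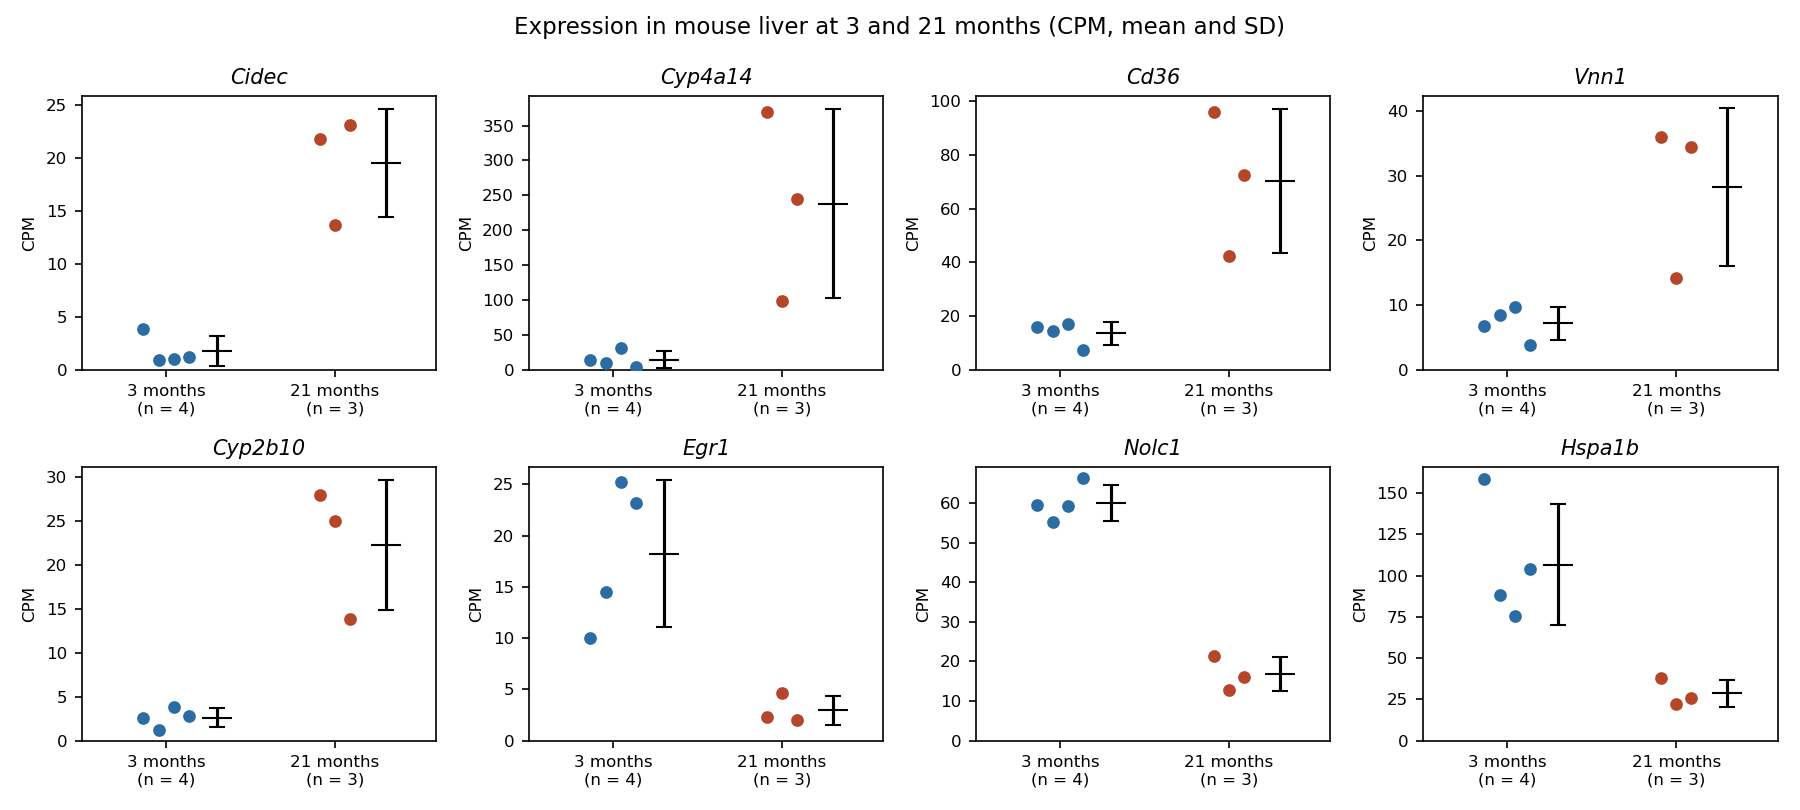
Expression of 8 named genes in each library, in CPM on linear axes from 0, with 3-month samples (n = 4) in blue and 21-month samples (n = 3) in red, and black bars for the mean and SD. The 3 samples at 21 months lie above every 3-month sample for Cidec, Cyp4a14, Cd36, Vnn1 and Cyp2b10 and below every one for Egr1, Nolc1 and Hspa1b.

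Of the 12 largest falls at a mean of at least 5 CPM, 4 were of major urinary protein rows, near-identical copies that share reads and whose single values are uncertain. LOC100048884, a Mup-like row, fell 40.2-fold, Mup7 5.87-fold, Mup14 4.22-fold and Mup21 3.34-fold. The immediate early transcription factor Egr1 fell from 18.3 ± 7.20 to 2.97 ± 1.43 CPM (log2 fold change -2.64 ± 0.42 SE, edgeR adjusted p = 0.00693). Gpr110 fell 5.58-fold, Zbtb7c 4.42-fold, the glucuronosyltransferase Ugt2b38 4.17-fold, the epithelial adhesion gene Cdh1 4.11-fold, Cyp2a4 4.02-fold and the heat shock gene Hspa1b 3.69-fold. Nolc1, a nucleolar phosphoprotein, fell from 60.1 ± 4.62 to 16.8 ± 4.31 CPM (edgeR adjusted p = 1.3e-05). The smallest p-values among falls also included the nucleolar helicase Ddx21 (2.09-fold), Mfap1b (2.93-fold) and Pdcd11 (1.93-fold), which acts in ribosomal RNA processing. The call of Cdh1 was lost without 3-month replicate 2 or 21-month replicate 3 (edgeR adjusted p = 0.0533 and 0.0795), and that of Hspa1b without 21-month replicate 2 or 3 (0.0605 and 0.0684).

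Of the 34 lists tested by camera, 20 passed with the preset correlation, 14 higher and 6 lower at 21 months, and 0 passed with the estimated correlation. Other splits of the same 7 libraries called 5 to 19 lists with the preset correlation, so a camera call alone carried little weight. Of the 20 lists, 11 had a larger shift in the real split than in any other of the 35 (p = 0.0286 by exact permutation, the smallest possible). They were the lipid droplet, fatty acid synthesis, xenobiotic, male-biased, female-biased, circadian, interferon, B cell, heat shock, nucleosome remodelling and lysosome lists. If the replicate numbers mark pairs, only 8 splits part all 3, too few for a p under 0.05. The member counts that follow come from edgeR's test over all genes, which called 11.3% of the genes tested, both directions together.

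**Figure D2:**
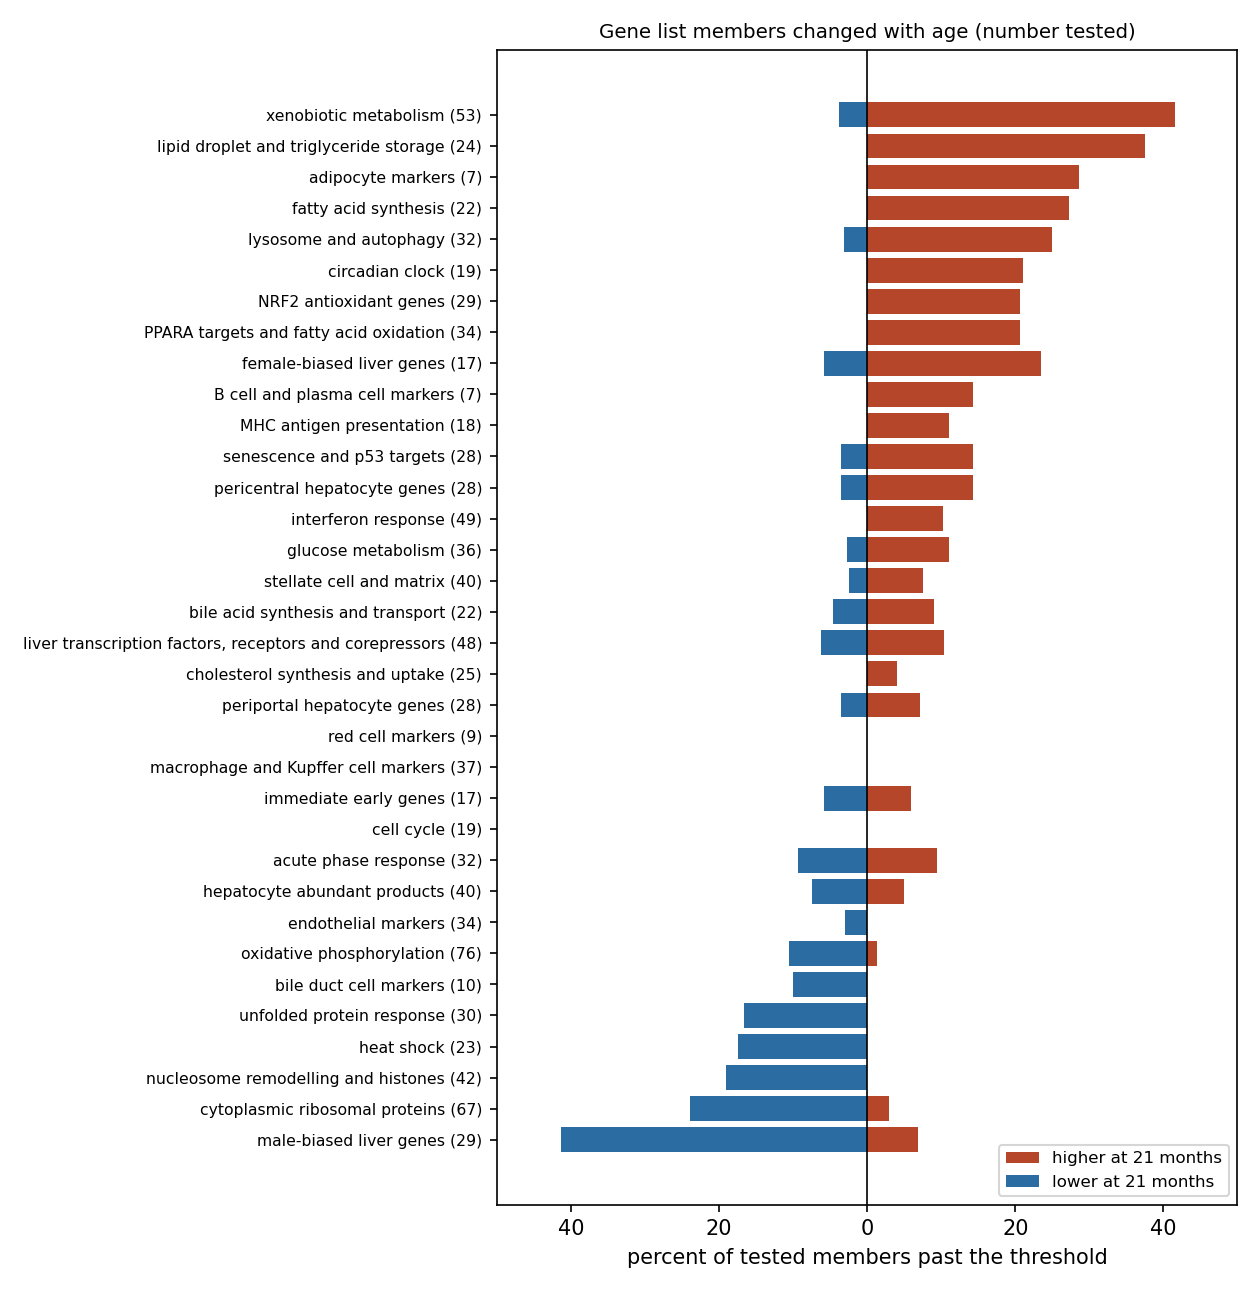
Percent of the tested members of each of the 34 gene lists that were higher (red, to the right of 0) or lower (blue, to the left) at 21 months by edgeR's test, on a linear axis, with the number tested in parentheses. Xenobiotic metabolism (22 of 53 higher) and male-biased liver genes (12 of 29 lower) lie at the ends.

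In the lipid droplet and triglyceride storage list, 9 of 24 tested members rose and 0 fell (12 and 0 adjusted over the list alone), with a median log2 fold change of 0.38 (camera adjusted p = 4.8e-09; adjusted p = 0.311 with an estimated correlation). They were led by Fitm1, Cidea, Cidec and Cideb, the last at 1.42-fold, and included Dgat2 and Agpat2 of triglyceride synthesis, chosen after their values were seen. With Cidea at the lower bound of its ratio the median was 0.38 as well, since 1 extreme member hardly moves a median. In the fatty acid synthesis list, 6 of 22 rose and 0 fell (8 and 0 adjusted over the list alone; camera adjusted p = 9.8e-06; adjusted p = 0.363 with an estimated correlation). They included Srebf1, a lipogenic regulator (log2 fold change 0.58), the elongase Elovl5 (2.11-fold) and Pnpla3 (5.22-fold). Pnpla3 stood at 0.912, 0.686, 0.405 and 0 CPM in 3-month replicates 1 to 4, near the floor, so its fold is uncertain. In the PPARA target and fatty acid oxidation list, 7 of 34 rose and 0 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.000149; adjusted p = 0.485 with an estimated correlation), among them Acot4 (2.83-fold) and the peroxisome gene Pex11a (1.53-fold). Of 7 adipocyte markers tested, 2 rose, Cidec and Pparg, both also expressed in hepatocytes (3 adjusted over the list alone; camera adjusted p = 0.00474; adjusted p = 0.363 with an estimated correlation). Cholesterol synthesis did not pass (camera adjusted p = 0.397), with 1 of 25 members higher and 0 lower (also 1 and 0 adjusted over the list alone); the list passed without 3-month replicate 1 (0.0392) and with fragment length as a covariate (0.00483).

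Of 53 tested genes of foreign-compound metabolism, 22 rose and 2 fell (27 and 5 adjusted over the list alone), with a median log2 fold change of 0.51 (camera adjusted p = 3.2e-12; adjusted p = 0.363 with an estimated correlation). Ugt3a1 rose 2.49-fold and the glutathione transferases Gstt3 and Gstt1 2.62-fold and 1.78-fold, while Ugt2b38 and Cyp2a4 fell. Many members belong to the Cyp2b and Cyp2c families, whose copies share reads. Of 29 NRF2 antioxidant genes, 6 rose and 0 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.00297; adjusted p = 0.363 with an estimated correlation), including Nqo1 (2.61-fold), Srxn1 (1.65-fold) and Gpx4 (1.45-fold). In the pericentral list, 4 of 28 rose, among them Cyp2c37 (2.57-fold), Cyp2c50 (1.66-fold) and Aldh3a2 (1.94-fold), and 1 fell, Rnf43 (7 and 2 adjusted over the list alone). That list passed (camera adjusted p = 0.0342; adjusted p = 0.485 with an estimated correlation), but not without 3-month replicate 2 or 3 (0.0959 and 0.0551) or 21-month replicate 1 or 3 (0.0761 and 0.123), nor with fragment length as a covariate (0.298). The edgeR call of Rnf43 was lost without 3-month replicate 4 (0.0750), 21-month replicate 2 (0.0748) or 21-month replicate 3 (0.0612), and with the replicate block (0.0602). Of 28 periportal genes, 2 rose and 1 fell (3 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.676).

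Of 29 male-biased genes tested, 12 fell and 2 rose (17 and 2 adjusted over the list alone), with a median log2 fold change of -0.63 (camera adjusted p = 2.7e-11; adjusted p = 0.337 with an estimated correlation). Outside the Mup rows, 9 of 24 fell and 2 rose; among the falls was Nudt7, a peroxisomal hydrolase (1.76-fold). Of 17 female-biased genes tested, 4 rose and 1 fell (9 and 2 adjusted over the list alone; camera adjusted p = 0.000160; adjusted p = 0.363 with an estimated correlation). The rises were Cyp2b9, Cyp4a14, the receptor Ntrk2 (9.12-fold) and Hamp2 (2.17-fold), a hepcidin gene whose call was lost without 21-month replicate 3 (edgeR adjusted p = 0.0575). Cyp2a4, a female-biased gene, fell. Summed over 22 rows, the Mup genes took 5.50% to 9.77% of the scaled counts at 3 months and 3.49% to 4.19% at 21 months. That was a 1.94-fold fall (exact permutation p = 0.0286, two-sided, the smallest that 35 splits allow). With the replicate numbers taken as pairs, only 8 splits part all 3, too few for a p under 0.05.

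**Figure D3:**
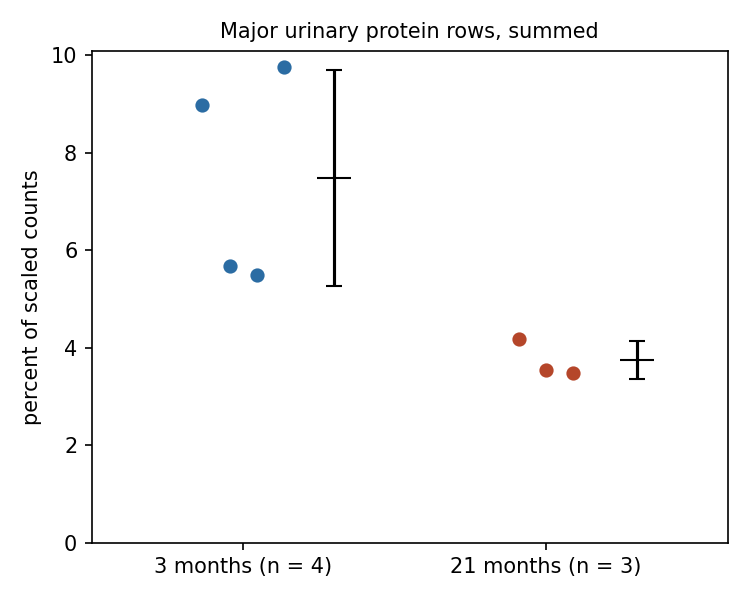
Summed share of the scaled counts taken by 22 major urinary protein rows in each library, in percent on a linear axis from 0, with 3-month samples (n = 4) in blue, 21-month samples (n = 3) in red and black bars for the mean and SD. The 21-month samples lie between 3.49% and 4.19%, below every 3-month sample.

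In the unfolded protein response list, 5 of 30 fell and 0 rose (7 and 0 adjusted over the list alone; camera adjusted p = 4.8e-05; adjusted p = 0.476 with an estimated correlation). Asns, which makes asparagine, fell 9.02-fold, the stress transcription factor Ddit3 2.49-fold and the kinase gene Eif2ak3 1.88-fold. At 21 months Asns stood at 0.296, 0.279 and 0.595 CPM in replicates 1, 2 and 3. In those libraries 3 counts are 0.296, 0.419 and 0.357 CPM, so the fold of Asns lies near the floor and is uncertain. Asns is a target of the amino acid response as well. Of 23 heat shock genes, 4 fell and 0 rose (also 4 and 0 adjusted over the list alone; camera adjusted p = 0.00282; adjusted p = 0.476 with an estimated correlation). Hsph1 fell 1.57-fold, and Bag3 fell 1.40-fold, a call lost without 21-month replicate 3 (edgeR adjusted p = 0.0537). The list did not pass without 21-month replicate 2 (camera adjusted p = 0.0530). Of 17 immediate early genes, Egr1 fell and Gadd45g rose (also 1 and 1 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.622). The call of Gadd45g was lost without 3-month replicate 2 or 4 (edgeR adjusted p = 0.0686 and 0.0679) and with the replicate block (0.0662).

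Of 67 cytoplasmic ribosomal protein genes, 16 fell and 2 rose (19 and 2 adjusted over the list alone), with a median log2 fold change of -0.17 (camera adjusted p = 8.2e-06; adjusted p = 0.533 with an estimated correlation). Rpl35 fell 1.65-fold and Rps28 1.33-fold, the latter call lost without 21-month replicate 3 (edgeR adjusted p = 0.0672), while Rpl39 rose 1.74-fold. Of 42 nucleosome remodelling and histone genes, 8 fell and 0 rose (also 8 and 0 adjusted over the list alone; camera adjusted p = 0.00833; adjusted p = 0.311 with an estimated correlation). Chd3 fell 1.42-fold and Chd1 1.47-fold. Of 76 oxidative phosphorylation genes, 8 fell and 1 rose (also 8 and 1 adjusted over the list alone), including Ndufs5 (1.61-fold) and Ndufa13 (1.49-fold) of complex I. That list passed (camera adjusted p = 0.0364; adjusted p = 0.894 with an estimated correlation), but not without 3-month replicate 1 or 4 (0.0786 and 0.166) or 21-month replicate 2 or 3 (0.516 and 0.435), nor with the replicate block (0.110), a minimum of 5 CPM (0.0766) or fragment length as a covariate (0.971).

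In the interferon response list, 5 of 49 rose and 0 fell (also 5 and 0 adjusted over the list alone), with a median log2 fold change of 0.32 (camera adjusted p = 5.7e-05; adjusted p = 0.363 with an estimated correlation). Oasl1 rose 2.57-fold, Irgm2 1.76-fold and the regulator Irf7 1.73-fold. Of 18 genes of MHC antigen presentation, 2 rose and 0 fell (also 2 and 0 adjusted over the list alone; camera adjusted p = 0.000317; adjusted p = 0.363 with an estimated correlation). They were H2-Q1 (log2 fold change 1.67) and H2-Q7 (0.58), near-identical copies whose values are uncertain; the call of H2-Q7 was lost without 3-month replicate 1 or 4 (edgeR adjusted p = 0.0595 and 0.0672) or 21-month replicate 2 (0.0639). H2-L, a class I row outside the list and chosen after its values were seen, stood at 8.43 ± 1.95 CPM at 3 months and at 0.887, 0 and 0 CPM in the 21-month replicates 1, 2 and 3. As an H2 row, its single value is uncertain too. A loss of expression was not told apart from reads given to another copy. Of 7 B and plasma cell markers tested, 1 rose, Igj, the joining chain of secreted antibodies (also 1 adjusted over the list alone), with 6 counts over the 3-month group and 50, 168 and 32 in the 21-month replicates 1, 2 and 3 (edgeR adjusted p = 0.0426). Its call was lost without any of the 3-month replicates 1, 2, 3 and 4 or without 21-month replicate 1 (edgeR adjusted p = 0.0564 to 0.129). It was also lost with library-size scaling (edgeR adjusted p = 0.0535) and no filter on low counts (0.0706). Limma voom without and with sample weights did not call Igj either (limma adjusted p = 0.110 and 0.0709). That list passed (camera adjusted p = 0.0462; adjusted p = 0.485 with an estimated correlation), but not without 3-month replicate 1, 3 or 4 (0.204, 0.0551 and 0.0514), with RLE (0.0503) or library-size scaling (0.0611), with ribosomal RNA rows removed (0.0581) or with fragment length as a covariate (0.132). None of the 4 T and NK cell markers or 2 neutrophil markers tested by edgeR passed, with too few members for camera (also 0 adjusted over each list alone). Of the lymphocyte transcripts below the filter, Cd3e had 6 counts over the 3-month group and 22 over the 21-month group. Cd8a had 8 and 17, Nkg7 5 and 17, and Ccl5 16 and 60. In CPM each was higher in every 21-month library, but they were named after their values were seen, from a list of 38. The other members below the filter were not tallied. Counts were few, down to 4 for Nkg7 in 21-month replicate 1, so the separation is uncertain. Of 37 macrophage and Kupffer cell markers, 0 passed in edgeR's test (also 0 adjusted over the list alone; camera adjusted p = 0.371), but camera called the list higher without 3-month replicate 2 (adjusted p = 0.0416) or 21-month replicate 1 (6.1e-06).

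Markers of other cell types follow, to be read beside the 11.3% of all tested genes that were called. Of 40 stellate cell and matrix genes, 3 rose and 1 fell (also 3 and 1 adjusted over the list alone; camera adjusted p = 0.622), with Dcn 1.63-fold and Cygb 2.13-fold higher; the list's median and mean lay below 0 (-0.04 and -0.02) and camera's direction was up. Of 34 endothelial markers, 1 fell, Lyve1 (0 adjusted over the list alone; camera adjusted p = 0.622). The call of Lyve1 was lost without 3-month replicate 2 (edgeR adjusted p = 0.106), 21-month replicate 1 (0.0982) or 21-month replicate 3 (0.142), and the list passed as lower with the replicate block (camera adjusted p = 0.0341) and without 21-month replicate 2 (0.0294). Of 10 bile duct markers, Sox9 fell 1.67-fold (also 1 adjusted over the list alone; camera adjusted p = 0.312). The 9 red cell markers gave 0 calls (also 0 adjusted over the list alone; camera adjusted p = 0.657), and the 1 exocrine pancreas marker tested, Cela1, stood at 13.4 ± 2.01 CPM at 3 months and 13.8 ± 1.26 CPM at 21 months and was not called (0 adjusted over the list alone). Of 40 hepatocyte products, 2 rose and 3 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.657). Albumin, Alb, rose 1.43-fold, a call lost without 3-month replicate 1 (edgeR adjusted p = 0.0852), 3 (0.0502) or 4 (0.0528) or 21-month replicate 3 (0.0998).

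Of 32 lysosome and autophagy genes, 8 rose and 1 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.00502; adjusted p = 0.363 with an estimated correlation), led by Lipa, the lysosomal acid lipase (1.69-fold), and the protease gene Ctsc (1.45-fold). Of 19 circadian clock genes, 4 rose and 0 fell (5 and 2 adjusted over the list alone), including Ccrn4l, Nr1d1 (1.95-fold) and Nr1d2 (1.93-fold). The clock list passed (camera adjusted p = 0.0363; adjusted p = 0.363 with an estimated correlation), but not without 3-month replicate 2 (0.0815) or 21-month replicate 1 (0.0897), nor at a minimum of 5 CPM (0.0766) or with fragment length as a covariate (0.0742). Of 28 senescence and p53 genes, 4 rose and 1 fell (5 and 1 adjusted over the list alone), including Trp53inp1 (1.58-fold) and Ei24 (1.40-fold). That list passed narrowly (camera adjusted p = 0.0425; adjusted p = 0.363 with an estimated correlation), but not without 3-month replicate 3 or 4 (0.0896 and 0.0891) or 21-month replicate 1 or 3 (0.0733 and 0.0621), nor with the replicate block (0.110), library-size scaling (0.0564), no filter on low counts (0.0816) or a minimum of 1 CPM (0.0594). The cell cycle list did not pass (camera adjusted p = 0.163), with 0 of 19 members called by edgeR (also 0 adjusted over the list alone); it passed without 3-month replicate 1 (0.0301), without 21-month replicate 3 (0.00411), with no filter on low counts (0.00289) and with fragment length as a covariate (0.000573). Of 36 glucose metabolism genes, 4 rose, among them Slc2a2 (1.41-fold) and G6pc (1.48-fold), and 1 fell (also 4 and 1 adjusted over the list alone; camera adjusted p = 0.0757); the list passed without 3-month replicate 4 (0.0495) or 21-month replicate 3 (0.0487). Of 32 acute phase genes, 3 rose and 3 fell (5 and 4 adjusted over the list alone; camera adjusted p = 0.676), with Crp 1.47-fold higher; the median was 0.04, the mean -0.11 and camera's direction up. Of 22 bile acid genes, 2 rose and 1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.312), with Slc10a1, the bile salt uptake carrier, 1.59-fold higher.

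Of 48 liver transcription factors, receptors and corepressors, 5 rose and 3 fell (also 5 and 3 adjusted over the list alone; camera adjusted p = 0.517). Cebpb rose 1.64-fold, and Prox1 fell 1.45-fold. Foxa2, a forkhead factor of hepatocytes, stood at 23.9 ± 2.89 CPM at 3 months and 34.7 ± 15.8 CPM at 21 months (log2 fold change 0.54 ± 0.27 SE, edgeR adjusted p = 0.261). The higher mean rested on replicate 2, with 26.7, 52.9 and 24.5 CPM in 21-month replicates 1, 2 and 3 against 19.7 to 26.5 at 3 months. The histone deacetylase Hdac3 (log2 fold change 0.26 ± 0.11 SE, edgeR adjusted p = 0.154) and the fatty acid receptor Ppara (0.19 ± 0.09, 0.214) did not pass the test either. Pparg rose from 6.18 ± 0.99 to 10.0 ± 1.15 CPM (log2 fold change 0.69 ± 0.18 SE, edgeR adjusted p = 0.0232), a call lost without 3-month replicate 2 or 4 or 21-month replicate 2 or 3 (edgeR adjusted p = 0.0588 to 0.0679) and with the replicate block (0.0616). The cell cycle inhibitor Cdkn1a did not pass (log2 fold change -0.41 ± 0.24 SE, edgeR adjusted p = 0.319). Cdkn2a was below the filter, with 3 counts over the 3-month group and 27 over the 21-month group.

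The spread between samples was compared as the median SD of log2 CPM over genes. It was 0.196 at 21 months and 0.176 at 3 months, a difference of 0.020 (exact permutation p = 0.600 over 35 splits, two-sided). The difference was -0.045 without 21-month replicate 1, -0.016 without 21-month replicate 2 and 0.022 without 21-month replicate 3. A median SD tends to be lower in a smaller group, and the 21-month group was the smaller, more so with a sample left out. The negative values may therefore come from group size, and these comparisons cannot decide which age spread more. At the same group sizes, the sign still differed with the 21-month sample left out.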

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

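Among 120 named genes and 6 measures per library, compared over the 4 samples at 3 months, 8 genes had 1 sample whose gap to the rest was large against their range; chance alone gives about 5% of such groups. All values are CPM. Cyp2b9 stood at 0.162 (1 count) in 3-month replicate 4 and Cidea at 0.365 (2 counts) in replicate 1, each at 0 in the others and under the floor of 3 counts, so these gaps carry no information. Cidec stood at 3.83 in replicate 1 against 0.944 to 1.14. In that library, fat cell transcripts stood higher too: Adipoq at 1.28 and Plin1 at 0.912, both at 0 in the others, and Cfd at 4.01 against 0.202 to 0.343. In replicate 4, Mup21 stood at 193 against 140 to 146, Rps28 at 86.7 against 79.2 to 79.7, and Cyp2c50 at 553 against 498 to 504. Lyve1 stood at 9.44 in replicate 2 against 3.47 to 3.90, and Chd1 at 23.7 in replicate 3 against 27.7 to 28.4. The 21-month group, with 3 samples, was not examined in this way.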

How the results depend on the processing

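The fits with ribosomal RNA rows removed, with the 6 paired samples and no block, and with fragment length as a covariate were chosen after the data were seen. The count of changed genes (1274) stayed within 1.5 times under RLE (1268), upper-quartile (1290) and library-size scaling (1032), DESeq2 (1098), voom (1272), each filter on low counts (1253 to 1411), removal of the 20 most abundant genes (1269), unrounded counts (1284), a non-robust fit (1222), the replicate block (1076) and removal of ribosomal RNA rows (1288). It was 2101 with voom and sample weights (983 higher, 1118 lower) and 66 (34 and 32) against a fold change of 1.5, a stricter hypothesis by construction. On the TPM scale, 266 genes were lower. Leaving out 1 sample gave 580 to 1642 changed genes (330 to 742 higher, 250 to 900 lower), lowest without 21-month replicate 3 and highest without 21-month replicate 1. The 6 paired samples without the block gave 745 (370 and 375), with fewer samples. Fragment length as a covariate gave 332 (179 and 153), of which 309 were also called without it; the covariate runs partly with age, which widens the errors. Where no construction is named, the cause was not tested.

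With an estimated correlation, 0 lists passed. Camera adjusted p-values then were 0.485 for PPARA targets, B cell and pericentral lists, 0.311 for lipid droplet and nucleosome remodelling, 0.337 for male-biased, 0.476 for unfolded protein response and heat shock, 0.533 for ribosomal protein and 0.894 for oxidative phosphorylation. They were 0.363 for fatty acid synthesis, xenobiotic, female-biased, circadian, interferon, MHC, adipocyte, senescence, NRF2 and lysosome lists. Larger correlations within lists widen camera's errors by construction, which cannot account for nucleosome remodelling. Its estimated correlation was -0.015, below the preset of 0.01, and its unadjusted camera p still rose from 0.00368 to 0.0183. Camera also uses fewer degrees of freedom when the correlation is estimated, which raises p-values by construction. How much of the rise for each list came from the correlation or from the degrees of freedom was not tested.

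Other changes of list calls follow as camera adjusted p, and their cause was not tested. Leaving out 1 sample gave 0.0392 to 0.883 for cholesterol synthesis, 0.00930 to 0.0897 for circadian clock, 0.00753 to 0.204 for B cell markers, 6.1e-06 to 0.766 for macrophage markers, 0.0294 to 0.874 for endothelial markers, and 0.00411 to 0.784 for cell cycle. It gave 0.0276 to 0.0896 for senescence, 8.1e-07 to 0.516 for oxidative phosphorylation, 0.0487 to 0.177 for glucose metabolism, 0.000414 to 0.0530 for heat shock and 0.00111 to 0.123 for pericentral genes. The replicate block gave 0.0341 for endothelial markers and 0.110 for both senescence and oxidative phosphorylation. Of the named genes, 10 were not called in that fit: Cyp4a14, Abcc3, Nlrc5, Pparg, Mat1a, Ndufb7, Uqcrh, Pfkfb3, Gadd45g and Rnf43. All 10 were also lost in the same 6 samples without the block, where 26 were lost. Against the fit to all samples, the fit with the block changed no other call of a list or named gene. That fit also left out the unpaired sample, so these losses cannot be credited to the block. Within the same 6 samples, the block ended no call of a named gene. There, 1076 genes changed with the block and 745 without it. Fragment length as a covariate ended the calls of 56 named genes and the test against a fold change of 1.5 those of 87. Limma on log2(TPM + 1) ended those of 23, among them Chd1, Chd3 and Prox1 (limma adjusted p = 0.140, 0.0760 and 0.0745). The paired samples without the block gave 0.0514 for B cell markers, 0.0891 for senescence, 0.166 for oxidative phosphorylation and 0.0495 for glucose metabolism. Fragment length as a covariate gave 0.00483 for cholesterol synthesis, 0.000573 for cell cycle, 0.0742 for circadian clock, 0.132 for B cell markers, 0.971 for oxidative phosphorylation and 0.298 for pericentral genes. A minimum of 5 CPM gave 0.0766 for circadian clock and for oxidative phosphorylation. RLE scaling gave 0.0503, library-size scaling 0.0611 and removal of ribosomal RNA rows 0.0581 for B cell markers. For senescence, library-size scaling gave 0.0564, no filter 0.0816 and a minimum of 1 CPM 0.0594. For cell cycle, no filter gave 0.00289.

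Each of the 120 named genes kept its sign under those of the 25 alternatives that tested it, and 32 also kept their side of the threshold; some filters, the TPM scale and single left-out samples dropped a few of these genes. Sign changes of lists that passed under neither setting were not counted. Depth limits genes near the floor, and 46.3% of simulated 1.5-fold changes were recovered.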

Other observations

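The tests of a fasted state, of read exchange between Mup copies, of Gm2083 and of neighbouring genes, and the ribosome biogenesis, adipose, amino acid response and major urinary protein lists, were chosen only after the results were seen.

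Genes of ribosome biogenesis, which process and assemble ribosomal RNA in the nucleolus, were lower as a set. Of 120 tested members, 57 fell and 1 rose, Imp3 (86 and 1 adjusted over the list alone), with a median log2 fold change of -0.52 (camera p = 1.3e-33 with the preset correlation, p = 0.00107 with an estimated correlation). Against the mean of the 3-month libraries, the median member was -0.47, -0.60 and -0.51 in 21-month replicates 1, 2 and 3, while each 3-month library lay between -0.03 and 0.05 of the others. Of 30 amino acid response genes, Asns, Ddit3 and the tRNA synthetase genes Eprs, Sars and Tars fell and Cebpb rose (8 and 3 adjusted over the list alone), and the list did not pass (camera p = 0.258, and p = 0.523 with an estimated correlation). Of 22 major urinary protein rows, 9 fell and 0 rose (14 and 2 adjusted over the list alone; camera p = 1.3e-10, and p = 0.102 with an estimated correlation).

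Of 24 lipid droplet genes, 9 were higher at 21 months (camera adjusted p = 4.8e-09; adjusted p = 0.311 with an estimated correlation). Adipose tissue in the samples was argued against by Adipoq, abundant in fat cells, at 0.204 ± 0.257 CPM at 21 months beside Cidec at 19.5 ± 5.09 CPM. None of 9 tested adipose transcripts was called by edgeR (0 adjusted over the list alone, camera p = 0.352, and camera p = 0.542 with an estimated correlation). Of the 9, 4 had a log2 fold change below 0. Cfd stood at 2.96, 2.09 and 2.62 CPM in 21-month replicates 1, 2 and 3. In 3-month replicates 1 to 4 it stood at 4.01, 0.343, 0.202 and 0.325 CPM. The list of adipose transcripts leaves out Cidec and Pparg, and Adipoq and Plin1 lay below the filter, so the list cannot decide the question. The fixed adipocyte list passed (camera adjusted p = 0.00474, and 0.363 with an estimated correlation), with Cidec and Pparg called of 7 tested. A more fasted state at 21 months as the whole cause would lower fatty acid synthesis genes, of which 6 were called higher and 0 lower, although 7 of 34 PPARA targets and the gluconeogenic gene G6pc rose, as they would with fasting. Feeding of another kind, time of day and age itself were not tested and stay open, so a rise of hepatocyte lipid storage genes with age may be taken as a hypothesis only.

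Ribosome biogenesis genes were lower at 21 months. Shorter fragments, read from the shortfall of effective length, were argued against as the whole cause by a fit with that shortfall as a covariate. In that fit, the list's median relative to all genes was -0.506 (-0.521 without the covariate) and 108 of 120 members lay below 0. That fit called 22 members lower, with a median SE of 0.217 against 0.160, so single calls ended through wider errors. A scaling factor moves all genes of a library alike and was not tested as an explanation. Age and feeding state were not tested for this list and may each underlie the fall.

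The major urinary protein rows, summed, were lower at 21 months. Reads moved among the 22 rows would leave their sum alike, but the summed CPM was lower in every 21-month library (log2 ratio -0.955). Of the 24 members of the list, 22 were in the files. Reads lost to copies outside these rows, or not aligned, would lower the sum as well and were not tested. Gm2083 stood at 0 in each 3-month library and at 3021, 937 and 801 CPM at 21 months. It was not called (edgeR adjusted p = 0.0665). Against the floor of 0.106 CPM over the 3-month group, it was at least 7539-fold higher in each 21-month library. That floor covers counting error only, not reads divided between near-identical copies, so it does not bound the gene's own fold. LOC100048884 stood at 2.48% of its 3-month mean. A difference between the animals in Mup copies or sequence may give such a switch and cannot be told apart from a change in expression, since no genotypes were used. Age was not tested apart from these.

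Raised genes were tested for lying side by side. The fullest window of 20 neighbouring tested genes held 7 raised genes, at the Ugt1a genes, a number reached in a share of 0.2 of 10000 random orders, so random placement was not excluded. For lowered genes the fullest window held 8, in the Mup cluster on chromosome 4, a number reached in a share of 0.03 of the orders.

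The grouping of the libraries was tested by all 35 splits into 4 and 3. In 1 of 35, the real one, as many genes changed (1274, highest other 5). The same held for genes higher (615, highest other 2) and lower (659, highest other 3). These counts come from the same fit, and 1 of 35 is the smallest share that the splits allow. No other split came near, but the test cannot exclude chance. For lists, 1 of 35 gave as many (20), but the highest other split gave 19. Among the 8 splits that part all 3 replicate pairs, the others called 0 genes and 5 to 19 lists, and 8 splits are too few for a share under 0.05.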
